A study of Mus musculus with 9 samples.

How the data were processed

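RNA from osteocyte-enriched tibial shafts of CD-1 mice was measured on Affymetrix mouse expression arrays in 3 groups of 3 arrays. The groups were age-matched virgin mice, mice on day 12 of lactation, and mice on day 7 after weaning forced on lactation day 12, called post-lactation. Per the labels the mice were 16 to 18 weeks old, litters held 8 to 13 pups, and the shafts were freed of periosteum and marrow and then digested in several rounds with collagenase, trypsin and EDTA to strip cells off their surfaces before RNA extraction. The group of each array was taken from its title. The source field of the post-lactation arrays reads virgin, in conflict with their titles, and 1 sentence of the extraction text speaks of femurs where all other fields give tibiae. No label states whether each array came from a separate mouse, so the p-values measure the spread between these samples.

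The deposited table holds log2 values, 1 for each of 45101 probe sets and each array, summarised by RMA per the submitters' processing notes. The series design text names GenePattern and Bioconductor. The versions, the annotation and any filter are not given in the sources used here. The values were checked: none was missing, they ran from 1.55 to 14.9, and no log was taken again. RMA, which corrects background, makes array distributions equal and fits a median polish, leaves shared distributions and exactly equal values among arrays processed together, so the columns were compared pairwise. The 9 arrays fell into 3 sets of 3, each with 1 array of every group. Set 1 held virgin 1, lactation 3 and post-lactation 1, set 2 held virgin 2, lactation 2 and post-lactation 3, and set 3 held virgin 3, lactation 1 and post-lactation 2. Within sets 2 and 3 between 36.1% and 44.1% of probe sets had exactly equal values in a pair of arrays, within set 1 between 2.50% and 2.72%, and between sets at most 2 probe sets. A simulated median polish of 2000 probe sets with 11 probes gave 57.75% equal pairs for 3 arrays, 0 for 4, 22.8% for 5 and 5.6% for 9. The lower share in set 1 leaves open with which other arrays it was summarised. Ties give many dim probe sets a difference of exactly 0 within sets 2 and 3.

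Probe sets were assigned to genes with the table supplied for the array: 34958 named 1 gene, 932 named several and 9211 named none. For each of 18194 genes the probe set with the highest mean over the 9 arrays was used, a choice that mattered for the 9012 genes with more than 1. Genes were compared with limma version 3.58.1 in R version 4.3.3, using lmFit and eBayes without a trend, group means, all 9 arrays and 6 residual degrees of freedom. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. There were 5 questions: lactation versus virgin, post-lactation versus lactation, post-lactation versus virgin, lactation versus the mean of the other groups, and the number of genes called in lactation that were called in the opposite direction after weaning. Differences are on the log2 scale and named as later or lactating group minus the other. Errors of means are SDs between arrays, and errors of differences are the SEs of the fit.

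Lists of genes were tested with limma's camera at a preset correlation of 0.01, adjusted over 34 lists with at least 5 measured genes. Beside this stand camera with the correlation estimated for each list, using statmod version 1.5.0, and directional fry. The function lists were resorption effectors, V-ATPase subunits, osteocyte genes, osteoblast and bone matrix genes, signals to osteoclasts, parathyroid hormone with vitamin D and mineral handling, Wnt, TGF-beta and BMP, sex steroid with prolactin and growth hormone response, matrix proteases, lysosome and autophagy, oxidative phosphorylation, glycolysis and hypoxia, protein secretion and unfolded protein response, immediate early and heat shock genes, cell division, interferon response, cholesterol and fatty acid synthesis, and ribosomal proteins. The cell type lists covered osteoclast identity, macrophages, neutrophils with their precursors, erythroid cells, B lymphocytes, T and NK lymphocytes, megakaryocytes, skeletal muscle, endothelium, adipocytes, chondrocytes, periosteum with tendon, marrow stroma, Schwann cells and milk proteins. Of 879 members written, 802 were found, 9 of them through a synonym. Acp5, Ctsk, Atp6v0d2, Atp6v1g1, Slc9b2, Mmp13 and Slc36a2 are known to have been reported from these samples. The resorption and V-ATPase lists were therefore also counted without them. Mmp13 is also in the lists of matrix proteases and of parathyroid hormone with vitamin D, which were not counted without it.

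The questions, the test, the lists, the rule for naming genes and the alternatives were fixed before the data were examined. The rule named a fixed set of bone genes in every comparison, of which Bglap had no probe set of its own, up to 8 rises and 8 falls among called genes whose groups did not overlap and whose higher mean exceeded the 40th percentile of 4.87, with clone names left out, and up to 4 members of each list. The alternatives were a variance trend with robust fitting, a fit of only the groups compared, array weights, filters on dim genes, other ways from probe sets to genes, repeated quantile normalization, equal array medians, the replicate number as a block, a minimum change of 1.5-fold, and each array left out in turn. The array set as a block, also without virgin 1 or without set 1, was added after seeing the data, as was the use of that percentile as the level below which a fold is given as a lower bound.

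Replicate numbers did not pair the arrays. After group means were removed, arrays with the same number correlated across genes between -0.413 and 0.670, and those of the same set between 0.468 and 0.734. All 9 arrays correlated best with an array of their own set, and 1 with an array of its own number.

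Each fit was tested on simulated data with the gene-wise spread it estimated from these samples. The offsets between array sets were part of the simulated data only for the fit with the set as a block. For lactation versus virgin it recovered 32.8% of 67 genes changed by 2-fold, 80.6% of those changed by 4-fold and 100% of 66 changed by 8-fold, with 7 false calls. The set block recovered 64.2% at 2-fold, with 14 false calls. Recovery at 2-fold was 37.3% for post-lactation versus lactation, with 8 false calls, and 28.4% for post-lactation versus virgin, with 6. A list shifted in simulation was found, and 0 of the other lists were called. Genes were drawn independently in that simulation, so it cannot show how often camera calls lists of correlated genes. The 9 arrays carry no counts, and their number limits the precision.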

Results

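Transcript levels were measured in osteocyte-enriched shafts of the tibia from virgin, lactating and post-lactation mice, with 3 arrays in each group. The purpose stated for the series was to find genes by which osteocytes remodel the bone matrix around their own lacunae. Array medians were 4.32 to 4.34 on the log2 scale in set 1, 4.80 to 4.82 in set 2 and 4.57 in set 3, and each set held 1 array of each group, so differences are also given within sets and with the set as a block. Where a group mean lay below 4.87, the 40th percentile of gene means, the fold against it is given as at least the value against that level. The number of arrays limits the precision of every value.

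Virgin 1 stood apart from the other two virgin arrays in its cell markers. Its level of Sost, the Wnt inhibitor made by osteocytes, was 8.14 against 13.39 in virgin 2 and 13.55 in virgin 3. The mean of the osteocyte genes, expressed as log2 above the array's median, was 3.17 in virgin 1, 4.30 in virgin 2 and 4.62 in virgin 3. On that scale the neutrophil list stood at 7.67, 6.91 and 6.67 in these arrays, and the B lymphocyte list at 2.03, 3.40 and 3.30.

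**Figure D1:**
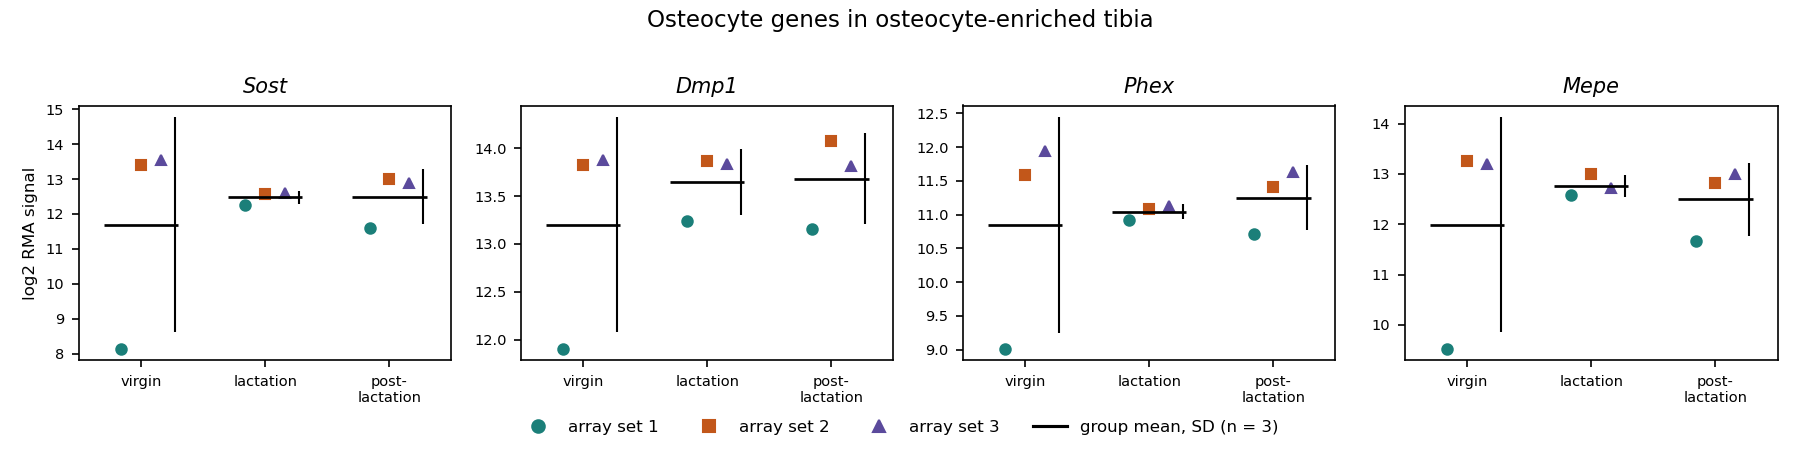
Log2 signal of the osteocyte genes Sost, Dmp1, Phex and Mepe in each of the 9 arrays, grouped as virgin, lactation and post-lactation; symbols mark the 3 array sets and bars give the mean and SD of 3 arrays. Sost was 8.14 in virgin 1 and 13.39 and 13.55 in the other virgin arrays.

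The comparison of lactation with virgin asks which genes osteocytes turn up or down while milk production draws on bone mineral. Genes for dissolving bone had higher mean signals in lactation, although no single gene passed the threshold. Ctsk, which encodes the collagen-degrading protease cathepsin K, averaged 10.46 ± 0.55 (SD, n = 3) in virgin and 12.29 ± 0.47 in lactation arrays, 3.57-fold higher. Acp5, the gene of tartrate-resistant acid phosphatase, averaged 10.85 ± 0.54 and 12.59 ± 0.65, 3.35-fold higher. Atp6v0d2, a proton pump subunit of bone-resorbing cells, averaged 7.51 ± 0.40 and 9.15 ± 0.22, 3.12-fold higher. The sodium/proton exchanger gene Slc9b2 was 3.49-fold higher. Mmp13, a collagenase, was 1.84-fold higher, and the carbonic anhydrase gene Car2 was 1.90-fold higher. Adjusted p was 0.861 for Ctsk, 1 for Acp5 and 0.494 for Atp6v0d2, and 0.0738, 0.0895 and 0.105 with the array set as a block. Their log2 differences within sets 1, 2 and 3 were 2.11, 2.13 and 1.27 for Ctsk, 2.15, 1.81 and 1.28 for Acp5 and 1.80, 1.90 and 1.22 for Atp6v0d2.

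Of 15 resorption effectors, 13 had a higher mean in lactation, 0 passed over all genes and 4 were higher when adjusted over the list alone. The median log2 difference was 0.56 and camera placed the list higher (adjusted p = 4.16e-16), a call lost at adjusted p = 0.328 with an estimated correlation. Within the sets the median was 0.70, 0.75 and 0.43. This list is not independent evidence, because it holds genes reported from these samples. Without them 8 of 10 members were higher, with a median of 0.45 and 0 members passing when adjusted over the list alone. With the set block 11 of the 15, and 7 of these 10, were higher when adjusted over the list alone. Among 22 V-ATPase subunits, which form the proton pump that acidifies lysosomes and resorption sites, 19 were higher, 0 passed over all genes and 1 was higher when adjusted over the list alone. Their median was 0.26 (adjusted p = 2.38e-08, and adjusted p = 0.581 with an estimated correlation), and 0.11, 0.36 and 0.29 within the sets. That list is not independent evidence either, and its 20 members outside the reported genes had a median of 0.19, with 17 higher and 0 passing when adjusted over the list alone. By that adjustment 7 of the 22 and 2 of these 20 were higher with the set block.

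Markers of osteoclasts and of red cell precursors moved with these genes. In the osteoclast identity list 15 of 19 genes had a higher mean, 0 passed over all genes and 2 were higher when adjusted over the list alone. Dcstamp, needed for osteoclast fusion, was 2.76-fold higher, Ocstamp 2.51-fold and Oscar 2.07-fold, and the list's median was 0.20 (adjusted p = 2.72e-06, and adjusted p = 0.581 with an estimated correlation). Within the sets that median was 0.34, 0.23 and 0.16, and it was 0.10 over all arrays with group means below 4.87 raised to that level. Adjusted over the list alone, 3 members were higher with the set block. All 18 erythroid genes had a higher mean, 0 passed over all genes and 15 were higher when adjusted over the list alone. Their median was 1.15 (adjusted p = 2.36e-38, and adjusted p = 0.156 with an estimated correlation) and 1.10, 0.84 and 1.43 within the sets, with Rhag 2.47-fold and Klf1 2.45-fold higher. Cell division genes had a median of 0.24, with 30 of 34 higher and 0 passing over all genes or when adjusted over the list alone (adjusted p = 2.38e-08, and adjusted p = 0.797 with an estimated correlation), and 0.04, 0.30 and 0.42 within the sets. Adjusted over the list alone, 17 erythroid and 7 cell division genes were higher with the set block.

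Genes of osteoblasts and bone matrix were higher in 26 of 32 cases, with 0 passing over all genes and 2 higher when adjusted over the list alone, or 12 with the set block. The collagen genes Col5a1 and Col12a1 were 1.95-fold and 2.21-fold higher, and Col1a1 was 1.55-fold higher (SE 0.29 log2, adjusted p = 1). The median was 0.43 (adjusted p = 1.12e-14, and adjusted p = 0.581 with an estimated correlation), within sets 0.72, 0.42 and 0.11, and 0.13 without virgin 1. The osteocyte genes had a median of 0.28 with 18 of 21 higher and 0 passing by either adjustment (adjusted p = 0.0488, and adjusted p = 0.799 with an estimated correlation). Without virgin 1 that median was -0.26 and camera placed the list lower (adjusted p = 0.00783), and within sets it was 1.08, 0 and -0.05. The call ended without virgin 2 (adjusted p = 0.0959), lactation 1 (0.67), lactation 3 (0.0719) and post-lactation 3 (0.0539), and the median was 0.75 without virgin 3. Sost differed by 0.78 (SE 1.11), Dmp1 by 0.44 (SE 0.47), Phex by 0.20 (SE 0.60) and Mepe by 0.77 (SE 0.80), none of them called. Without virgin 1 these 4 were -0.99, -0.20, -0.72 and -0.47, and a dimmer probe set of Sost, at a mean of 6.79, differed by -0.13 over all arrays. The hormone gene Fgf23 averaged below 4.87 in all 3 groups, so no difference is given for it in any comparison. The parathyroid hormone receptor gene Pth1r differed by 0.48 (SE 0.37), the osteoclast signal Tnfsf11 by 0.44 (SE 0.26) and its decoy receptor gene Tnfrsf11b by 0.20 (SE 0.67), and their adjusted p was 1 for each, as for Fgf23.

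**Figure D2:**
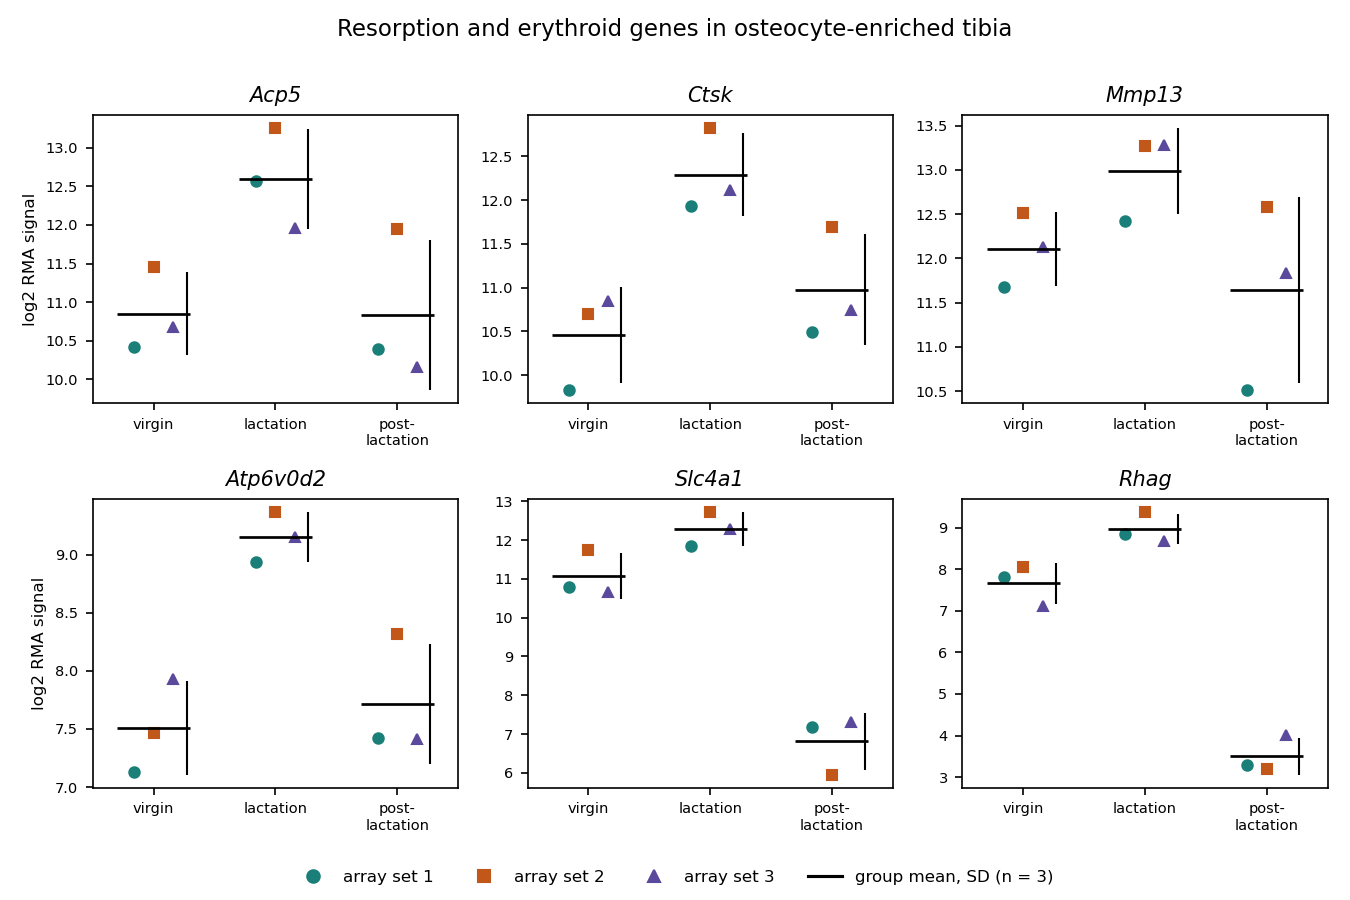
Log2 signal of Acp5, Ctsk, Mmp13, Atp6v0d2, Slc4a1 and Rhag in each of the 9 arrays, grouped as virgin, lactation and post-lactation; symbols mark the 3 array sets and bars give the mean and SD of 3 arrays. Ctsk averaged 10.46, 12.29 and 10.98 in the 3 groups, and Rhag 7.66, 8.97 and 3.51.

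Camera placed 4 further lists higher in lactation: matrix proteases (median 0.11), lysosome and autophagy (0.09), oxidative phosphorylation (0.12, with 42 of 50 genes higher) and megakaryocytes (0.22), with adjusted p of 0.00223, 0.0314, 0.000707 and 0.0296. With an estimated correlation their adjusted p was 0.797 for matrix proteases and 0.799 for the others. The matrix protease list holds Mmp13, which was reported from these samples and is in the resorption list, so it is not independent evidence. Camera placed 8 lists lower. Neutrophil genes had a median of -0.32 with 16 of 17 lower (adjusted p = 3.20e-08, and adjusted p = 0.581 with an estimated correlation), and interferon genes -0.19 with 22 of 26 lower (adjusted p = 4.60e-07, and adjusted p = 0.581 with an estimated correlation). The mean neutrophil level, log2 above the array's median, was 7.67 in virgin and 7.25 in lactation in set 1, and 6.91 and 6.37 in set 2. In set 3 it was 6.67 and 6.76, so no fall was seen there. The medians of the other 6 were -0.18 for glycolysis and hypoxia, -0.09 for immediate early and heat shock genes, -0.09 for chondrocytes, -0.08 for the sex steroid, prolactin and growth hormone response, -0.06 for marrow stroma and -0.04 for cholesterol and fatty acid synthesis, with adjusted p between 0.000991 and 0.0319. With an estimated correlation adjusted p was 0.799 for immediate early genes and 0.797 for the other 5. With group means below 4.87 raised to that level the chondrocyte median was 0, with 13 of 16 members concerned, and the sex steroid response median -0.01. In these 12 lists 0 genes passed over all genes by limma, and Glb1 of the lysosome list, 1.95-fold higher, was the single member past the threshold when adjusted over the list alone. The set block gave by that adjustment 6 matrix protease genes higher and 1 lower, 4 oxidative phosphorylation and 3 lysosome genes higher, and 0 in the other 9. Median, mean and test differed in sign for 4 lists that did not pass: TGF-beta and BMP, protein secretion, skeletal muscle and milk proteins, with medians of 0.00, -0.01, -0.01 and 0.05, means of -0.03, 0.01, 0.02 and -0.03, and camera direction down for each.

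By limma 0 of 18194 genes were called, 328 had an unadjusted p under 0.05 where chance gives 909.7, and the smallest adjusted p was 0.336. Of the 328, 275 were higher and 53 lower in lactation. Offsets between array sets enter the spread of the fit without the block. A count at or below the chance value there does not show an absence of change. With the array set as a block limma called 4 genes, all higher and with the same sign in all 3 sets, and 1457 had an unadjusted p under 0.05. That fit called 0 without virgin 1 (1853 with an unadjusted p under 0.05) and 0 without set 1 (1827). The 4 were the chemokine gene Cxcl3 (log2 difference at least 1.37), Dcstamp (1.46), Tlcd4 (at least 0.44) and the heme synthesis gene Cpox (1.14), of which Tlcd4 and Cpox were chosen after their values were seen. Camera called 19 lists, 0 with an estimated correlation, 0 with fry, 13 with the set block, and 10 without lactation 2. The set block ended the calls of osteocyte genes (adjusted p = 0.0848), cholesterol synthesis (0.102), chondrocytes (0.119), immediate early genes (0.138), megakaryocytes (0.23) and marrow stroma (0.238). Of the 19, 6 kept their call whichever array was left out: resorption effectors, V-ATPase subunits, osteoblast genes, interferon, osteoclast identity and erythroid genes. Of the 19 calls 9 ended without lactation 2 and 9 without virgin 3, 6 without virgin 2, 5 without lactation 1 and 5 without lactation 3, 4 ended or turned without virgin 1 and 1 ended without post-lactation 3. The median of the V-ATPase list was 0.06 without lactation 2. That of osteoclast identity was 0.06 without lactation 2, 0.12 without virgin 1, 0.30 without virgin 2 and 0.31 without lactation 3, and that of interferon -0.33 without virgin 1, -0.06 without virgin 2 and -0.34 without lactation 2. The cell division call ended without virgin 3 (adjusted p = 0.43) and its median was 0.09 without lactation 2, and the neutrophil call ended without virgin 1 (adjusted p = 0.269) and without lactation 2 (adjusted p = 0.133).

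The weaker list calls in lactation versus virgin moved with single arrays. The matrix protease median ran from -0.07 without virgin 1 to 0.34 without lactation 3, and its call ended without virgin 2 (adjusted p = 0.0996) and lactation 1 (0.123). Lysosome genes ran from -0.04 without lactation 2 to 0.17 without lactation 3, with the call ended without virgin 2 (adjusted p = 0.392), virgin 3 (0.308), lactation 1 (0.0559), lactation 2 (0.0868) and lactation 3 (0.0754). Oxidative phosphorylation ran from -0.02 without lactation 2 (adjusted p = 0.0607) to 0.25 without virgin 2, and its call also ended without virgin 3 (0.0724). Megakaryocyte genes ran from -0.08 without virgin 1 (adjusted p = 0.488) to 0.60 without virgin 2, and were not called without virgin 3 (0.322), lactation 2 (0.133) or lactation 3 (0.436). Glycolysis ran from -0.27 without lactation 2 (adjusted p = 0.0804) to -0.04 without virgin 2. Immediate early genes ran from -0.32 without virgin 1 to 0.11 without lactation 3 (adjusted p = 0.436), and were not called without virgin 2 (0.199), virgin 3 (0.524) or lactation 2 (0.22). For the sex steroid response the range was -0.28 without virgin 1 to 0.01 without virgin 2, and the call ended without virgin 3 (adjusted p = 0.43) and lactation 2 (0.161). Chondrocyte genes ran from -0.32 without lactation 2 to 0.04 without virgin 2 (adjusted p = 0.0631), and were not called without virgin 3 (0.516) or lactation 1 (0.0853). Marrow stroma ran from -0.22 without virgin 1 to 0.09 without virgin 2 (adjusted p = 0.0631), and was not called without virgin 3 (0.173), lactation 2 (0.489) or lactation 3 (0.223). Cholesterol synthesis ran from -0.13 without lactation 2 (adjusted p = 0.54) to -0.01 without lactation 1 (0.111), and was not called without virgin 1 (0.267) or virgin 3 (0.128). Lists not called over all arrays passed on leaving out virgin 1 (B lymphocytes at -0.65, TGF-beta and BMP at -0.26, Wnt at -0.18, periosteum at -0.18, Schwann cells at -0.39), virgin 2 (B lymphocytes at 0.46), virgin 3 (Wnt at 0.23, periosteum at 0.23, B lymphocytes at 0.26, parathyroid hormone and vitamin D at 0.16, TGF-beta and BMP at 0.14, macrophages at -0.16) and lactation 1 (adipocytes at -0.08).

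The comparison of post-lactation with lactation asks what changes in osteocytes once weaning ends the demand for milk calcium. Red cell genes fell most. Slc4a1, the anion exchanger of the red cell membrane, fell from 12.28 ± 0.44 (SD, n = 3) to 6.81 ± 0.74, 44.4-fold lower, and Rhag, the Rh-associated glycoprotein, from 8.97 ± 0.36 to 3.51 ± 0.44, at least 17.2-fold lower. Car2, a carbonic anhydrase of both osteoclasts and red cells, fell from 12.39 ± 0.52 to 8.70 ± 0.42, 12.9-fold lower. Adjusted p was 7.52e-05 for Slc4a1, 3.58e-05 for Rhag and 0.000460 for Car2, and 0.00322, 0.00121 and 0.00121 with the array set as a block. Sfrp2, a secreted Wnt modulator, rose from 4.21 ± 0.17 to 6.38 ± 0.25, at least 2.85-fold (adjusted p = 0.000706, and 0.00274 with the set block).

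Of 18 erythroid genes 16 fell over all genes and 17 fell when adjusted over the list alone. Hemgn fell 29.5-fold, Klf1 27.9-fold and Alas2 27.1-fold, Trim10 at least 23.2-fold and Kel at least 13.9-fold, and Cldn13, outside the list, at least 18.8-fold. The median was -4.08 (adjusted p = 2.94e-86, adjusted p = 0.0194 with an estimated correlation, and 0.0015 by fry), and -3.99, -4.61 and -3.62 within the sets. It was -3.93 with group means below 4.87 raised to that level, which concerned 5 members. A dimmer probe set of Slc4a1, at a mean of 3.48, differed by -0.43 and was not called. Cell division genes were lower in 34 of 34 cases, with Rrm2, which makes DNA precursors, the 1 gene that fell over all genes (2.68-fold, adjusted p = 0.0192) and 15 that fell when adjusted over the list alone. Their median was -0.72 (adjusted p = 4.49e-26, and adjusted p = 0.548 with an estimated correlation), and -0.79, -0.74 and -0.63 within the sets, and with the set block 17 fell over all genes and 25 when adjusted over the list alone.

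The resorption effectors were lower in 13 of 15 cases, with Car2 the 1 that fell over all genes and 5 that fell when adjusted over the list alone. Their median was -0.40 (adjusted p = 4.97e-08, and adjusted p = 0.615 with an estimated correlation), and -0.37, -0.50 and -0.37 within the sets. Acp5 was 3.39-fold lower (adjusted p = 0.248), Ctsk 2.49-fold lower (adjusted p = 0.298) and Mmp13 2.54-fold lower (adjusted p = 0.545), and with the set block they fell with adjusted p of 0.0119, 0.0297 and 0.0467. Without post-lactation 3 Acp5 passed as well (adjusted p = 0.0301). The list is not independent evidence, and without the reported genes 8 of 10 members were lower, with a median of -0.28 and Car2 the 1 that fell by either adjustment. With the set block 10 of the 15 and 4 of these 10 fell when adjusted over the list alone. Car2 is also in the erythroid list. V-ATPase subunits were lower in 20 of 22 cases, 0 passed over all genes and 1 fell when adjusted over the list alone. Their median was -0.19 (adjusted p = 0.000813, and adjusted p = 0.823 with an estimated correlation), and -0.28, -0.14 and -0.19 within the sets. Atp6v0d2 differed by -1.44 (SE 0.30, adjusted p = 0.0644, and 0.0312 with the set block, 0.0194 without post-lactation 3). That list is not independent evidence either, and its other 20 members had a median of -0.15, with 18 lower and 0 passing when adjusted over the list alone, and with the set block 4 of the 22 and 1 of these 20 fell by that adjustment. Osteoclast identity had a median of 0.08, a mean of -0.14 and a camera direction of down (adjusted p = 0.59), and with the set block Dcstamp and Oscar differed by -1.22 and -1.25 on the log2 scale and fell past the threshold (adjusted p = 0.00363 and 0.0180).

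Camera placed the B lymphocyte list higher after weaning, with 19 of 20 genes higher, 0 passing over all genes, and 4 higher and 1 lower when adjusted over the list alone. The lymphocyte precursor genes Vpreb1, Dntt and Rag1 were 3.92-fold, 3.03-fold and 3.08-fold higher, and the list's median was 1.06 (adjusted p = 1.82e-09, and adjusted p = 0.696 with an estimated correlation), and 1.22, 0.91 and 0.93 within the sets. Neutrophil genes had a median of 0.31, with 10 of 17 higher, 0 passing by either adjustment and 6 higher with the set block when adjusted over the list alone (adjusted p = 0.00332, and adjusted p = 0.823 with an estimated correlation). Adipocyte genes had a median of 0.52 and marrow stroma genes 0.44, with 12 of 16 and 10 of 11 higher and 0 passing by either adjustment (adjusted p = 7.43e-05 and 6.12e-06, and adjusted p = 0.668 and 0.548 with an estimated correlation). Raising group means below 4.87 to that level gave an adipocyte median of 0.33. Within the sets it was 1.07, 0.28 and 0, and the stroma median 0.95, 0.43 and 0.04.

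Oxidative phosphorylation genes had a median of -0.19, with 45 of 50 lower and 0 passing by either adjustment, and with the set block 13 lower and 1 higher when adjusted over the list alone (adjusted p = 0.000793, and adjusted p = 0.926 with an estimated correlation). Medians of 6 more lists that camera placed higher were 0.18 for TGF-beta and BMP, 0.17 for sex steroid, prolactin and growth hormone response, 0.15 for immediate early and heat shock genes, 0.13 for signals to osteoclasts (0.02 with group means below 4.87 raised to that level), 0.13 for macrophages and 0.10 for endothelium. Their adjusted p was 0.016, 0.00788, 0.00288, 0.0129, 0.0101 and 0.0104, and with an estimated correlation adjusted p was 0.926, 0.823, 0.828, 0.823, 0.828 and 0.828. By limma 0 genes of these 6 passed by either adjustment, and with the set block 1 immediate early gene rose over all genes and 3 macrophage genes were higher and 1 lower when adjusted over the list alone. Outside called lists, Asns, the asparagine synthetase gene in the protein secretion list, fell 3.68-fold (adjusted p = 0.00564), and the interferon-induced gene Rsad2 fell 4.67-fold (adjusted p = 0.0377). Osteocyte and osteoblast lists had medians of 0.02 and 0.01 (adjusted p = 0.9 for each), with a mean of -0.05 and a camera direction of up for the osteocyte list. Sost differed by 0.02 (SE 1.11), Dmp1 by 0.04 (SE 0.47), Phex by 0.21 (SE 0.60), Mepe by -0.27 (SE 0.80), Pth1r by -0.25 (SE 0.37), Tnfsf11 by 0.17 (SE 0.26), Tnfrsf11b by -0.35 (SE 0.67), Col1a1 by -0.02 (SE 0.29) and Atp6v1g1 by -0.58 (SE 0.25). A dimmer probe set of Tnfsf11, at a mean of 5.60, differed by -0.10. None of these was called, although Atp6v1g1 fell with the set block (adjusted p = 0.0437).

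By limma 129 of 18194 genes were called, 126 lower and 3 higher, and 921 had an unadjusted p under 0.05 where chance gives 909.7. The other rises were Olfm4 2.53-fold (adjusted p = 0.0381) and Lrmp 2.06-fold (adjusted p = 0.0428), calls that ended on leaving out any of 7 and of 8 of the 9 arrays, with adjusted p up to 0.219 without lactation 2 for Olfm4 and 0.199 without post-lactation 1 for Lrmp. With the array set as a block 642 were called, 544 lower and 98 higher, among them all 129, and 2740 had an unadjusted p under 0.05. Each of the 129 had the same sign in all 3 sets. The count was 76 without lactation 2 and 80 without post-lactation 2, and 0 with the block on sets 2 and 3 alone, where 2567 had an unadjusted p under 0.05 and 2 residual degrees of freedom were left. Camera called 15 lists, 1 with an estimated correlation and 1 with fry, the erythroid list in both, and 14 with the set block, which ended the call of signals to osteoclasts (adjusted p = 0.0969). Of the 15, 8 kept their call whichever array was left out, 5 ended without lactation 2 and 5 without post-lactation 1, and 1 each without lactation 1, lactation 3, post-lactation 2 and post-lactation 3. The resorption median was -0.62 without lactation 1 and -0.21 without post-lactation 2, and the V-ATPase median -0.29 without lactation 1, -0.06 without lactation 2 and -0.37 without post-lactation 3. The oxidative phosphorylation median was -0.05 without lactation 2, -0.07 without post-lactation 1 and -0.32 without post-lactation 3. The neutrophil call ended without lactation 2 (adjusted p = 0.557) and post-lactation 1 (adjusted p = 0.0876), and its median was 0.20 without lactation 3 and 0.17 without post-lactation 3. The adipocyte call ended without post-lactation 1 (adjusted p = 0.0756), and without lactation 3 the adipocyte median was 0.32 and the stroma median 0.27.

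The weaker list calls after weaning also moved with single arrays. Signals to osteoclasts ran from -0.08 without post-lactation 3 to 0.29 without lactation 2 (adjusted p = 0.0552), and their call also ended without post-lactation 1 (0.0876). TGF-beta and BMP genes ran from 0.05 without lactation 3 (adjusted p = 0.0538) to 0.32 without post-lactation 1, and were not called without lactation 2 (0.254) or post-lactation 2 (0.174). Sex steroid response genes ran from 0.03 without lactation 3 to 0.28 without lactation 2 (adjusted p = 0.0828), and were not called without post-lactation 1 (0.143). Immediate early genes ran from 0.00 without lactation 3 to 0.31 without post-lactation 1 and kept their call. Macrophage genes ran from -0.03 without post-lactation 3 (adjusted p = 0.0506) to 0.32 without lactation 2, and were not called without lactation 1 (0.0511). Endothelium ran from 0.05 without post-lactation 1 (adjusted p = 0.709) to 0.23 without post-lactation 2, and was not called without lactation 2 (0.173). Lists not called over all arrays passed without lactation 1 (Wnt at 0.08), post-lactation 2 (megakaryocytes at 0.50) and post-lactation 3 (interferon at 0.06).

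**Figure D3:**
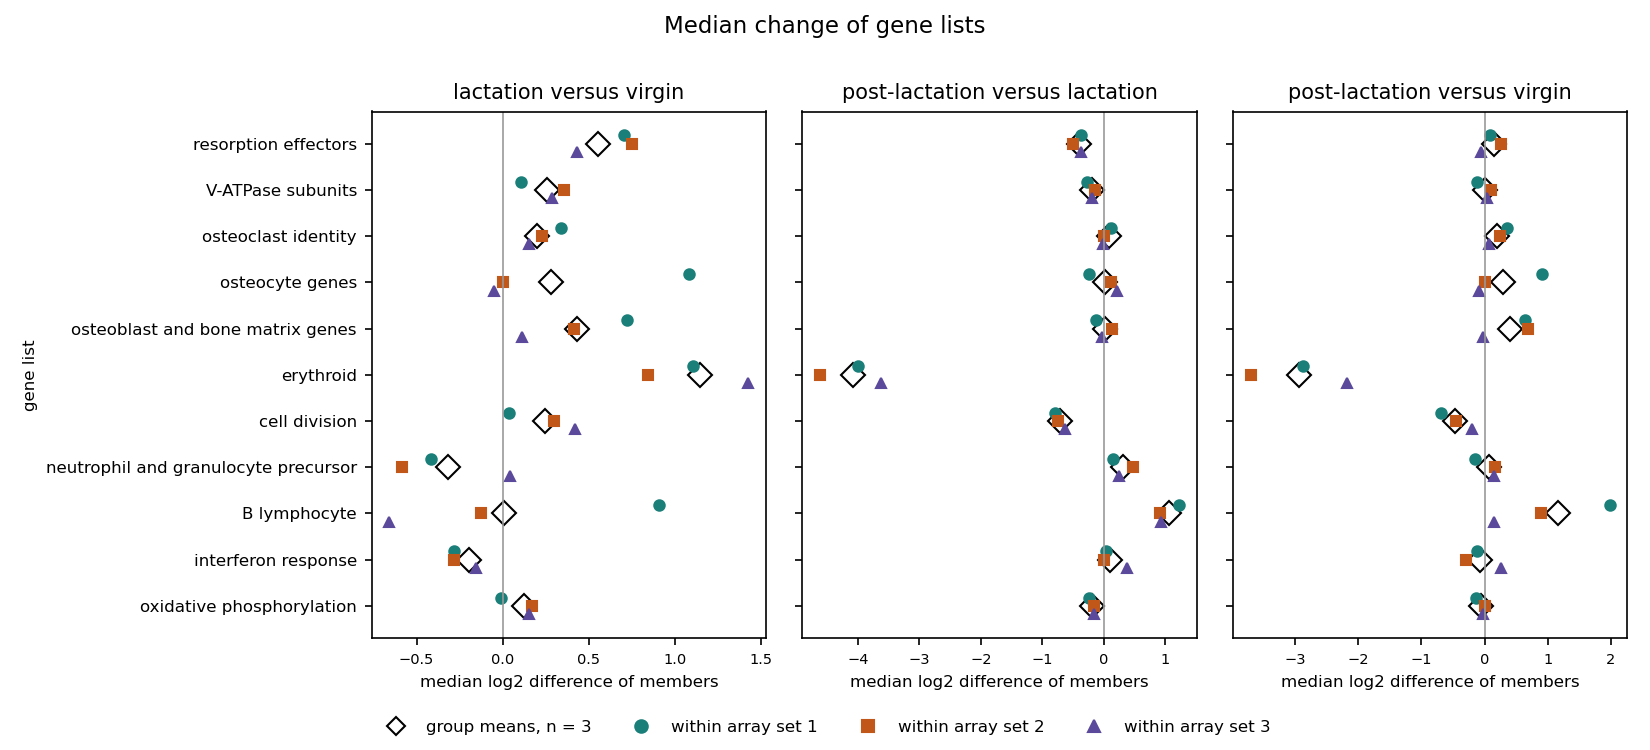
Median log2 difference of 11 gene lists in 3 comparisons, as the difference of group means over all 9 arrays and within each of the 3 array sets. The erythroid median was -4.08 for post-lactation minus lactation and -2.94 for post-lactation minus virgin.

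The comparison of post-lactation with virgin asks whether the tissue had returned to its state before pregnancy. Red cell genes were lower than in virgin mice, and of 15 resorption effectors Car2 alone was called. Slc4a1 fell from 11.06 ± 0.59 (SD, n = 3) to 6.81 ± 0.74, 19.1-fold lower, and Rhag from 7.66 ± 0.50 to 3.51 ± 0.44, at least 6.95-fold lower, with adjusted p of 0.00253 and 0.000659, and 0.0315 and 0.0186 with the set block. Car2 fell 6.77-fold (adjusted p = 0.0129, and 0.0184 with the set block), a call that ended without post-lactation 1 (adjusted p = 0.0823) and post-lactation 2 (adjusted p = 0.0507). Acp5 differed by -0.02 (SE 0.48), Ctsk by 0.52 (SE 0.37), Mmp13 by -0.46 (SE 0.46), Atp6v0d2 by 0.21 (SE 0.30) and Atp6v1g1 by 0.27 (SE 0.25), none of them called. The chemokine gene Cxcl3 rose from 4.70 ± 0.31 to 6.09 ± 0.20, at least 2.33-fold (adjusted p = 0.0364, and 0.0148 with the set block), and stood at 6.24 ± 0.12 in lactation. The Cxcl3 call ended on leaving out any of 8 of the 9 arrays, with adjusted p up to 0.196 without post-lactation 2.

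Of 18 erythroid genes 12 fell over all genes and 16 fell when adjusted over the list alone. Hemgn fell 13.3-fold, Klf1 11.4-fold and Alas2 11.2-fold, Trim10 at least 10.01-fold and Kel at least 5.60-fold, and Cldn13, outside the list, at least 8.71-fold. With the set block the call of Alas2 ended (adjusted p = 0.0665). The median was -2.94 (adjusted p = 1.78e-103, adjusted p = 0.0118 with an estimated correlation, and 0.00934 by fry), and -2.87, -3.70 and -2.18 within the sets, and it was -2.78 with group means below 4.87 raised to that level. Cell division genes were lower in 34 of 34 cases with 0 passing by either adjustment, while 19 fell with the set block when adjusted over the list alone. Their median was -0.46 (adjusted p = 4.68e-21, and adjusted p = 0.428 with an estimated correlation), and -0.69, -0.45 and -0.19 within the sets. It was -0.31 without virgin 2 or without post-lactation 2.

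B lymphocyte genes had a median of 1.16, with 17 of 20 higher, 0 passing by either adjustment, and 6 higher and 1 lower with the set block when adjusted over the list alone (adjusted p = 2.73e-16, and adjusted p = 0.428 with an estimated correlation), within sets 1.98, 0.89 and 0.15, and 0.37 without virgin 1. Osteoblast and matrix genes had a median of 0.40, with 29 of 32 higher, 0 passing by either adjustment and 7 higher with the set block when adjusted over the list alone (adjusted p = 1.25e-15, and adjusted p = 0.428 with an estimated correlation). Within sets that median was 0.64, 0.69 and -0.02, and it was 0.11 without virgin 1 and 0.16 without post-lactation 3. Col1a1 was 1.53-fold higher (SE 0.29 log2, adjusted p = 1), and Col11a1, 2.06-fold higher, rose with the set block (adjusted p = 0.0280). The osteocyte list had a median of 0.30 with 18 of 21 higher and 0 passing by either adjustment (adjusted p = 0.0341, and adjusted p = 0.757 with an estimated correlation). Without virgin 1 that median was -0.41 and camera placed the list lower (adjusted p = 0.0112), and within sets it was 0.90, 0 and -0.09. The call ended without virgin 2 (adjusted p = 0.0602) and post-lactation 2 (0.743). Sost differed by 0.80 (SE 1.11), Dmp1 by 0.48 (SE 0.47), Phex by 0.40 (SE 0.60), Mepe by 0.50 (SE 0.80), Pth1r by 0.24 (SE 0.37), Tnfsf11 by 0.61 (SE 0.26) and Tnfrsf11b by -0.15 (SE 0.67), none of them called. Leaving out virgin 1 gave -0.98 for Sost, -0.17 for Dmp1, -0.51 for Phex and -0.73 for Mepe, and the dimmer Sost probe set differed by -0.13.

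Resorption effectors had a median of 0.15, a mean of -0.08 and a camera direction of up (adjusted p = 0.722), with Car2 the 1 that fell by either adjustment and 10 of 15 higher. The list is not independent evidence, and without the reported genes its median was 0.12. V-ATPase subunits had a median of 0.00, with 12 of 22 higher (adjusted p = 0.32). Neutrophil genes had a median of 0.07, a mean of -0.07 and a camera direction of down (adjusted p = 0.599). Camera placed 11 more lists higher. Megakaryocytes had a median of 0.45, marrow stroma 0.32, adipocytes 0.27 and endothelium 0.21, and these 4 calls ended without post-lactation 1, with medians of 0.17, 0.18, 0.15 and 0.14 and adjusted p of 0.752, 0.156, 0.233 and 0.385. Within the sets the medians were 1.57, -0.17 and 0 for megakaryocytes, 0.70, 0.10 and -0.02 for stroma, 0.62, 0.02 and 0 for adipocytes and 0.65, 0.02 and -0.12 for endothelium. Medians of the other 7 were 0.20 for signals to osteoclasts, 0.20 for osteoclast identity, 0.20 for macrophages, 0.16 for T and NK lymphocytes, 0.13 for TGF-beta and BMP, 0.11 for the Wnt pathway and 0.06 for matrix proteases. Group means below 4.87 raised to that level gave medians of 0.10 for adipocytes, 0.06 for T and NK lymphocytes, 0 for the Wnt pathway and, of the lists placed lower, -0.02 for interferon. Adjusted p lay between 0.000116 and 0.0305 for these 11, and with an estimated correlation adjusted p lay between 0.428 and 0.757. It placed 4 more lists lower: cholesterol and fatty acid synthesis at -0.20, glycolysis and hypoxia at -0.12, interferon at -0.08 and protein secretion with the unfolded protein response at -0.06, with adjusted p between 0.000835 and 0.0496. With an estimated correlation adjusted p was 0.536, 0.757, 0.757 and 0.842. In these 15 lists 0 genes passed over all genes, and 2 Wnt pathway genes were higher when adjusted over the list alone. The set block gave by that adjustment 2 Wnt pathway genes and 1 osteoclast identity gene higher, and 1 megakaryocyte and 1 glycolysis gene lower.

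By limma 32 genes were called, 31 lower and 1 higher, and 381 had an unadjusted p under 0.05 where chance gives 909.7. With the array set as a block 82 were called, 77 lower and 5 higher, 30 of the 32 among them, and 1476 had an unadjusted p under 0.05. All 32 had the same sign in all 3 sets. The count was 21 without virgin 1, 13 without post-lactation 1, 13 without post-lactation 2 and 16 without post-lactation 3. With the set block it was 4 without virgin 1, and 0 on sets 2 and 3 alone, where 1604 had an unadjusted p under 0.05. Camera called 20 lists, 1 with an estimated correlation and 1 with fry, the erythroid list in both, and 19 with the set block, which ended the calls of matrix proteases (adjusted p = 0.088) and interferon (0.126) and added immediate early genes (0.0409). Of the 20, 8 kept their call whichever array was left out: osteoblast genes, signals to osteoclasts, cell division, cholesterol synthesis, osteoclast identity, erythroid, B lymphocyte and T and NK lymphocyte genes. Calls ended or turned for 9 lists without virgin 1, 6 without post-lactation 1, 5 without virgin 2, 5 without post-lactation 2, 3 without virgin 3, 3 without post-lactation 3, 1 without lactation 1 and 1 without lactation 2.

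Several of these list calls against virgin moved with single arrays. Megakaryocyte genes ran from 0.11 without virgin 1 (adjusted p = 0.0772) to 0.85 without virgin 2, and were not called without virgin 3 (0.0746). Endothelium ran from 0.03 without virgin 1 (adjusted p = 0.11) to 0.35 without virgin 2, adipocytes had a median of 0.17 without virgin 1 and 0.42 without post-lactation 2, and stroma 0.16 without virgin 1. Wnt genes ran from -0.14 without virgin 1 (adjusted p = 0.407) to 0.26 without virgin 3. TGF-beta and BMP genes ran from -0.13 without virgin 1 (adjusted p = 0.114) to 0.32 without virgin 3, and were not called without post-lactation 2 (0.137). The matrix protease range was -0.13 without virgin 1 (adjusted p = 0.206) to 0.18 without virgin 2 (0.305), and the call ended without post-lactation 2 (0.137) and post-lactation 3 (0.149). Glycolysis ran from -0.20 without post-lactation 3 to 0.02 without virgin 2, and was not called without virgin 1 (adjusted p = 0.0773) or post-lactation 2 (0.0678). Interferon genes ran from -0.18 without virgin 1 (adjusted p = 0.263) to 0.13 without virgin 2 (0.272), and were not called without post-lactation 1 (0.118) or post-lactation 3 (0.554). Macrophage genes ran from 0.04 without post-lactation 3 (adjusted p = 0.101) to 0.26 without virgin 2 (0.0538), and were not called without virgin 3 (0.57).

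Protein secretion ran from -0.19 without post-lactation 3 to 0.04 without virgin 2 (adjusted p = 0.0624). Its call also ended without virgin 1 (0.109), virgin 3 (0.183), lactation 1 (0.0538), lactation 2 (0.0518), post-lactation 1 (0.333) and post-lactation 2 (0.0906). Of lists that kept their call, signals to osteoclasts ran from 0.01 without post-lactation 3 to 0.41 without virgin 2, and osteoclast identity from 0.06 without virgin 1 to 0.32 without virgin 2. T and NK lymphocytes ran from 0.07 without post-lactation 3 to 0.24 without virgin 2, and cholesterol synthesis from -0.34 without post-lactation 3 to -0.07 without post-lactation 1. Lists not called over all arrays passed without virgin 1 (chondrocytes at -0.26, lysosome at -0.02, neutrophils at 0.01), virgin 2 (immediate early genes at 0.25), virgin 3 (periosteum at 0.22, immediate early genes at 0.06, neutrophils at 0.08) and lactation 3 (immediate early genes at 0.07).

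Not called in any pairwise comparison were parathyroid hormone with vitamin D and mineral handling, ribosomal proteins, skeletal muscle, periosteum with tendon, Schwann cells and milk proteins. In lactation versus virgin their medians were 0.04, -0.01, -0.01, 0.01, -0.02 and 0.05, with adjusted p of 0.231, 0.755, 0.897, 0.779, 0.363 and 0.471. Muscle and milk protein genes lay below the array median on average in each of the 9 arrays, muscle by 0.37 to 0.55 and milk proteins by 0.42 to 0.66 on the log2 scale.

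Lactation set against the mean of the other groups asks which genes stand apart during lactation itself. Red cell genes rose most by this measure, with post-lactation levels below virgin levels in each case named. Rhag averaged 7.66 ± 0.50 (SD, n = 3) in virgin, 8.97 ± 0.36 in lactation and 3.51 ± 0.44 in post-lactation arrays and rose at least 6.51-fold (adjusted p = 0.00127, and 0.00508 with the set block). Slc4a1 rose 10.2-fold, Klf1 8.27-fold, Hemgn 8.09-fold and Alas2 8.08-fold, Trim10 at least 7.34-fold and Tspan8, outside the erythroid list, at least 4.16-fold. These folds draw largely on the fall after weaning. Against virgin alone the log2 differences were 1.22 for Slc4a1, 1.29 for Klf1, 1.15 for Hemgn and 1.27 for Alas2, none called. Dimmer probe sets of Tspan8, at means of 2.65 to 4.71, differed by -0.95 to -0.07 for post-lactation minus lactation, none called. Sfrp2 was at least 1.82-fold lower (adjusted p = 0.00567). Of 18 erythroid genes 15 rose over all genes and 17 when adjusted over the list alone, and the median was 2.63 (adjusted p = 7.20e-79, adjusted p = 0.0247 with an estimated correlation, and 0.00817 by fry), and 2.58, 2.76 and 2.55 within the sets, and it was 2.57 with group means below 4.87 raised to that level.

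Atp6v0d2 rose 2.91-fold against the other groups (adjusted p = 0.0254, and 0.0188 with the set block), with within-set log2 differences of 1.66, 1.48 and 1.48. Its call ended without lactation 1 (adjusted p = 0.115), lactation 2 (0.196), lactation 3 (0.0839), post-lactation 1 (0.066) and post-lactation 2 (0.0715). Car2, which is also in the erythroid list, rose 4.95-fold (adjusted p = 0.00838), a call that ended without lactation 1 (adjusted p = 0.0511) and lactation 2 (adjusted p = 0.0699). The fold of Car2 draws largely on its fall after weaning, a log2 difference of -3.69. Against virgin alone its difference was 0.93, not called. Acp5 was 3.37-fold higher (adjusted p = 0.172, 0.00986 with the set block and 0.0276 without post-lactation 3) and Ctsk 2.98-fold higher (adjusted p = 0.0849, 0.0122 with the set block and 0.0348 without post-lactation 3). Of 15 resorption effectors, not independent evidence, 1 rose over all genes and 7 when adjusted over the list alone, and 2 of the 10 outside the reported genes did so (11 of 15 and 7 of 10 with the set block). Their median was 0.47 (adjusted p = 1.25e-12, and adjusted p = 0.545 with an estimated correlation), and 0.40, 0.63 and 0.40 within the sets. Of 34 cell division genes 0 rose over all genes, 8 when adjusted over the list alone, and with the set block 13 over all genes and 22 over the list alone. Their median was 0.46 (adjusted p = 1.47e-20, and adjusted p = 0.652 with an estimated correlation).

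Other lists placed higher were V-ATPase subunits (0.20), osteoblast genes (0.27), oxidative phosphorylation (0.16) and osteoclast identity (0.02), with adjusted p between 6.25e-06 and 0.022, and between 0.769 and 0.88 with an estimated correlation. Placed lower were neutrophils (-0.25), B lymphocytes (-0.45), marrow stroma (-0.28), adipocytes (-0.33), interferon (-0.13), immediate early genes (-0.13), sex steroid response (-0.14) and macrophages (-0.13), with adjusted p between 1.30e-05 and 0.0278, and between 0.652 and 0.88 with an estimated correlation. Median, mean and test differed in sign for Wnt, cholesterol synthesis, T and NK lymphocytes, skeletal muscle and endothelium, none of them called, with medians of 0.01, 0.03, 0.03, -0.01 and 0.01. By limma 86 genes were called, 85 higher and 1 lower, and 716 had an unadjusted p under 0.05. With the array set as a block 434 were called, all 86 among them, and 2416 had an unadjusted p under 0.05. The count was 29 without lactation 2, 41 without lactation 3, 43 without lactation 1, 49 without post-lactation 2 and 54 without post-lactation 1, and 0 with the block on sets 2 and 3 alone, where 2445 had an unadjusted p under 0.05. Camera called 15 lists, and the erythroid list was the 1 called with an estimated correlation and with fry. It called 13 with the set block, which ended the calls of osteoclast identity and adipocytes (adjusted p = 0.0651 for each). Raised to 4.87, group means below it gave medians of 0.00 for osteoclast identity, -0.07 for interferon and -0.19 for adipocytes.

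Most of the list calls for lactation against the other groups also moved with single arrays. The osteoblast median was 0.10 without virgin 1, where the call ended (adjusted p = 0.0655), and that of osteoclast identity ran from -0.10 without lactation 2 (adjusted p = 0.0534) to 0.16 without lactation 3. V-ATPase subunits ran from 0.07 without lactation 2 to 0.34 without lactation 1, and oxidative phosphorylation from 0.02 without lactation 2 to 0.24 without lactation 3. Macrophage genes ran from -0.30 without lactation 2 to 0.05 without lactation 3, and were not called without virgin 1 (adjusted p = 0.137), lactation 1 (0.153) or post-lactation 3 (0.0653). B lymphocyte genes ran from -0.87 without virgin 1 to -0.22 without virgin 2. Immediate early genes ran from -0.27 without virgin 1 to -0.01 without lactation 3 (adjusted p = 0.0793), and were not called without lactation 2 (0.0534). Adipocytes ran from -0.41 without post-lactation 2 to -0.08 without lactation 3, and were not called without lactation 2 (adjusted p = 0.052) or post-lactation 1 (0.0797). For the sex steroid response the range was -0.22 without lactation 2 (adjusted p = 0.0647) to -0.06 without lactation 3, and for interferon -0.27 without lactation 2 to -0.05 without virgin 2. The stroma median was -0.17 without lactation 3, and the neutrophil call ended without lactation 2 (adjusted p = 0.281). Lists not called over all arrays passed without virgin 1 (TGF-beta and BMP at -0.23, Wnt at -0.13, chondrocytes at -0.20, endothelium at -0.10, lysosome at 0.03), virgin 3 (glycolysis at -0.08, matrix proteases at 0.08, osteocyte genes at 0.33), lactation 1 (TGF-beta and BMP at -0.14), lactation 3 (glycolysis at -0.02, matrix proteases at 0.18), post-lactation 1 (megakaryocytes at 0.11), post-lactation 2 (chondrocytes at -0.13, endothelium at -0.12) and post-lactation 3 (endothelium at 0.01, placed lower).

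Genes that changed in lactation and turned back after weaning were counted from both comparisons. Tlcd4 was at least 1.36-fold higher in lactation than in virgin and at least 1.36-fold lower after weaning, Cpox differed by 1.14 on the log2 scale and was then at least 7.55-fold lower, and Dcstamp differed by 1.46 and -1.22. These 3 turned back with the array set as a block. Simulation of unchanged groups gave 0, but such groups give few calls in either comparison, so that value lends these 3 no support. When the fit with the set block left out virgin 1 or set 1, 0 genes turned back. Tlcd4 and Cpox were also lower after weaning than in virgin arrays by that fit (adjusted p = 0.00374 for each), Cpox by at least 3.42-fold, while both means of Tlcd4 lay below 4.87. With group means alone limma gave 0 such genes, because it called 0 in lactation versus virgin, and 243 had an unadjusted p under 0.05 with opposite signs in both. Across genes, which are not independent replicates, the 2 differences correlated at r = -0.679. Unchanged groups that share the lactation arrays gave -0.499 in simulation, and -0.503 with the spread of the set block. The covariance was -0.0528, against -0.0513 and -0.0151 in the 2 simulations. The first includes offsets between sets that cancel in both differences, so it overstates what the shared arrays give. The second leaves these offsets out, and the observed covariance differed from it by -0.03775. This argues against the shared arrays as the sole source of the covariance. Genes were drawn independently in both simulations, so the exact part of the shared arrays was left open.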

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

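The 7 tests of technical explanations in this part, on marrow, array sets, osteoclast RNA, RNA quality and osteocyte share, were chosen after the results they address were seen, and so were the splits made within array sets, which came with the set block. The splits of all arrays were planned. Outside the 18194 genes tested, and with the control probe sets of the array left out, 10092 probe sets had no gene or several genes in the annotation. They entered no comparison of the report. Among them limma called 16 in post-lactation versus lactation, all 16 lower, and 62 with the array set as a block. It called 5 in post-lactation versus virgin, all 5 lower, and 5 with the set block. These stood out as a signal in data the comparisons did not use, and no cause was tested.

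Erythroid genes fell after weaning, with a list median of -4.08. Less marrow left in the bones would have lowered other marrow lists too, and the lower of the neutrophil and B lymphocyte medians was 0.31, which argues against that as the cause. Separate normalization of the array sets is argued against by the smallest fall within a set, -3.62. Fewer red cell precursors after weaning, a difference between the groups of the design, may explain the pattern and stays a hypothesis, and loss of red cells in handling was not tested.

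Resorption effectors had a higher median in lactation, 0.56. RNA of osteoclasts left on the bone could explain it, since the median of 19 osteoclast identity genes lay at percentile 99.9 of random lists matched on expression, although the labels state that surface cells were digested off. Such random lists treat genes as independent, while the list was lost at adjusted p = 0.581 with an estimated correlation of 0.439, its median of 0.20 was 0.06 to 0.31 on leaving out 1 array and 0.10 with group means below 4.87 raised to that level, so this explanation stays open. For post-lactation minus lactation, raised in the same way, the resorption median was -0.40 but the osteoclast identity median 0.06. Dcstamp and Oscar of the identity list fell with the set block. Tyrobp, the member with the highest signal (signals of different probe sets do not rank abundance), averaged 11.69, 11.71 and 12.17 in virgin, lactation and post-lactation arrays, 2 members (Fos and Calcr) are also in other lists, and none was picked by the study from these samples. Separate normalization of the array sets is again argued against by the design, in which offsets between sets cancel, and the smallest rise within a set was 0.43. Expression by osteocytes themselves may contribute as well, since these arrays do not separate the cell types.

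Osteocyte genes were low in virgin 1. Degraded RNA is argued against by a 3' minus 5' signal of beta-actin of 0.73, the lowest of 9 arrays, of which the highest was 1.24. Its array set as the sole cause is argued against by lactation 3 of that set at 4.30, within the 4.18 to 4.62 of the 6 arrays of other sets, although post-lactation 1 at 3.99 lay below those 6, with virgin 1 at 3.17. A lower share of osteocyte RNA with all other cells raised alike would have raised all other markers, but the B lymphocyte level was -1.32 relative to the other virgin arrays. That value cannot decide about a lower share made up by some cells only. The neutrophil level was 7.67 in virgin 1 against 6.91 and 6.67 in virgin 2 and virgin 3. The osteoblast level was 3.87 against 4.17 and 4.46. A different makeup of cells in that sample stays open as a possible explanation, and no biological explanation was tested.

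Other splits of the arrays were counted for each number of called genes. For 2 groups of 3 there are 10 splits, too few for a share under 0.05. With group means alone 10 of 10 gave at least the real 0 in lactation versus virgin (highest other 0), 1 the 129 in post-lactation versus lactation (highest other 0) and 1 the 32 in post-lactation versus virgin (highest other 0). For lactation against the other groups 8 of 100 gave at least 86, so chance was not excluded. The highest other gave 9893, and all 7 others put a whole array set into 1 group, which points to the structure of the sets. The within-set splits below have no such splits. For genes that turned back 100 of 100 gave at least 0 (highest other 5554). A real count of 0, here and in lactation versus virgin, is reached by any split, so these counts cannot decide about chance. With the set as a block and splits made within sets, 4 of 100 gave at least 4 in lactation versus virgin (highest other 642). In post-lactation versus lactation 1 gave the 642 (highest other 82), and in post-lactation versus virgin 2 gave the 82 (highest other 642). In lactation against the others 1 gave the 434 (highest other 425). Each of these highest others was a set of the labelled groups under exchanged names, and splits that mix the groups gave at most 4, 2, 4 and 3. In lactation versus virgin 1 split that mixes the groups equalled the real 4, so chance was not excluded for that count. For the other counts the shares lay under 0.05 and 0 splits that mix the groups reached the real number. This argues against all 3 groups being alike. The splits redraw all 3 groups at once, so a difference of 1 group widens the spread in the mixed splits. They cannot decide about chance for a single comparison, such as post-lactation versus virgin.

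For called lists the 10 splits were again too few: 2 gave at least 19 in lactation versus virgin (highest other 19), 2 at least 15 in post-lactation versus lactation (highest other 18) and 2 at least 20 in post-lactation versus virgin (highest other 20). Against the mean of the others 23 of 100 gave at least 15 (highest other 20), and chance was not excluded. With the set block, in the same order, 42 of 100 gave at least 13 (highest other 21) and 32 at least 14 (highest other 21). Then 3 gave at least 19 (highest other 21) and 43 at least 13 (highest other 20). The share was under 0.05 for post-lactation versus virgin alone. There 2 splits that mix the groups gave at least 19 lists, with up to 21, and the set block with an estimated correlation called 0. Chance was therefore not excluded for any of these list counts.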

How the results depend on the processing

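The fits with the array set as a block, alone, without virgin 1, without the first set and with an estimated correlation, were chosen after seeing the data, and the other alternatives were planned. Under 21 settings 0 called results among 89 for named genes reversed, while values not called changed sign 90 times, in 29 of the 89. Of 102 list results 2 reversed, and the direction changed 69 times for lists not called in both fits. The 2 were the osteocyte median, which without virgin 1 was -0.26 (leave-one-out range -0.26 to 0.75) for lactation versus virgin and -0.41 (range -0.41 to 0.61) for post-lactation versus virgin. The cause was not tested. Genes called in lactation versus virgin numbered 0 by limma (328 at unadjusted p under 0.05), 2 with array weights, 1 after quantile normalization again, 1 with array medians made equal, 4 with the set block, 0 with it and without virgin 1 (1853 at unadjusted p under 0.05), 0 with it and without the first set (1827), and 0 without any 1 array. For post-lactation versus lactation the count was 129, 350 with array weights (all 129 among them), 205 after quantile normalization, 642 with the set block, 927 with it and without virgin 1, and 0 with it and without the first set (2567 at unadjusted p under 0.05), with a leave-one-out range of 76 to 138. For post-lactation versus virgin it was 32, 82, 4 and 0 with the 3 set block fits (1604 at unadjusted p under 0.05 in the last), and 13 to 34 on leaving out 1 array. Against the mean of the others it was 86, 192 with array weights, 57 with the mean of a gene's probe sets, 137 after quantile normalization, 137 with medians made equal, 434, 548 and 0 with the set block fits (2445 at unadjusted p under 0.05 in the last), and 29 to 103 on leaving out 1 array. Genes that turned back numbered 0, 1 with array weights, 3 with the set block, and 0 with it and without virgin 1 or without the first set. The zeros without the first set came with 2 residual degrees of freedom, and the cause of the other shifts was not tested. With the replicate block, which pairs arrays by number, the counts were 0, 118, 33, 90 and 0, and the lists called 19, 15, 20 and 16. Called lists numbered 19, 15, 20 and 15, and 0, 1, 1 and 1 with an estimated correlation, 0, 1, 1 and 1 with fry, and 0, 0, 0 and 0 with the set block and an estimated correlation. Lists called on leaving out 1 array ranged from 10 to 21 for lactation versus virgin, the lowest without lactation 2.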

Other observations

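Post-lactation 1 stood apart from the other post-lactation arrays in several marker lists, noticed after the values were seen. Its mean adipocyte level, log2 above the array's median, was 3.10 against 2.31 and 2.48, its marrow stroma level 5.31 against 4.61 and 4.70, its endothelium level 3.27 against 2.70 and 2.73, and its megakaryocyte level 4.59 against 3.30 and 3.73.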
